A study of Mus musculus with 6 samples.

How the data were processed

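Messenger RNA levels were measured by RNA sequencing of total RNA from mouse blast crisis chronic myeloid leukaemia (BC CML) cells, in 3 libraries carrying a short hairpin RNA against Amd1 (shAMD1) and 3 libraries carrying a hairpin against the bacterial lacZ gene (shlacZ), per the labels. Per the labels' protocols, the leukaemic cells came from the bone marrow of C57BL/6 mice, were sorted, and were grown with stem cell factor and thrombopoietin, and libraries followed a standard Illumina protocol. The aligner, the version of the counting tool, the annotation and the genome build are not given in the sources used here. The labels do not say whether the 3 libraries of a group came from separate mice or cultures. Any spread between libraries that enters the authors' p-values may therefore be technical, and it need not be all that these p-values measure.

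The authors deposited a table of 23997 genes and 3 subsets of it. Per the file headers, the columns are those of a Cuffdiff gene-level table, and the 2 value columns were read as FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of a library) from that layout and from their range. The authors pooled the 3 libraries of a group into a single FPKM value per group, so no value per library was analysed here. Per the file headers, the knockdown libraries behind the shAMD1 value are numbered 2, 3 and 4, whereas the labels number them 1, 2 and 3, so which labelled libraries they are is uncertain. The deposited log2 fold change is the log2 of the shAMD1 value over the shlacZ value, which was checked on all finite rows. The deposited p-value and q-value come from the authors' test of each gene. Their q-values were reproduced by a Benjamini-Hochberg adjustment over the 12425 genes that the authors tested, and are called adjusted p here. The smallest p in the authors' deposited table is 5e-05, which 639 tested genes share, with an adjusted p of 0.000972. The 3 subset tables hold exactly the tested genes with a finite fold change of at least 1.5, alone or with an adjusted p under 0.1 or an unadjusted p under 0.05. Positions in the table count from 0 at the start and were converted to count from 1. Of the 22500 symbols found in RefSeq's mouse assembly GRCm38.p6, 99.4% lay on the same chromosome and 50.2% had the same start, so the positions are those of GRCm38 gene models.

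Sequencing depth is unknown, since the files give no counts. FPKM sums over all genes were 727795 in shlacZ and 769997 in shAMD1. Without values per library, the planned limma fit, the camera list tests, principal components, the search for duplicate libraries, the fit with replicate numbers and the removal of single libraries could not be run. The authors' test was used in place of the planned one, and no error of a group value can be given. A gene was counted as called higher or lower when its adjusted p in the authors' deposited table was under 0.05. Folds were computed from the 2 group values, without a pseudocount. A total of 103 rows list several symbols, and 2688 tested rows share their locus with another row, so the reads of neighbouring or near-identical genes may have been split between rows by the authors' counting.

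Before the data were examined, 36 gene lists were fixed: pathways around polyamines, translation, stress, the cell cycle and metabolism, and markers of cell types that the marrow or the sort could hold. For each of the 34 lists with at least 5 tested members, the called members were counted, and the count was repeated with the authors' p adjusted over the list alone. The list's median log2 fold change was placed among 10000 random lists of the same size, matched on mean FPKM in 20 bins. That percentile describes these group values and is not a test across replicates. Genes were named by a rule fixed at the same time. Amd1 and Amd2 were always named, then the 12 largest rises and the 12 largest falls among called genes with a mean FPKM of at least 5, then up to 4 called members of each list with the smallest adjusted p. The rule left out symbols that are placeholders or that name a pseudogene or a non-coding RNA. This was read from the symbol and not from the annotated biotype, and the list of such symbols, with Rmrp and Rpph1 on it, was written after the data were examined. The rule also asked that replicates of the groups not overlap, which could not be applied. Ties at the smallest adjusted p were broken by the larger fold. Named genes outside the rule are marked as chosen after their values were seen.

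Alternatives tried were the limits of the subset tables, a mean FPKM of at least 5 with the adjustment repeated, all genes with a value above 0 in the adjustment, centring on the median, and pseudocounts of 1 and 0.1. Those added after the data were examined left out rows of several symbols or a shared locus, summed the Amd1 and Amd2 rows, and, for lists, used log2(FPKM + 1), the 1.5-fold limit, adjustment over the list alone, or removed the trend of fold change on transcript length and GC content (longest GENCODE M21 transcript, found for 99.3% of tested genes with a finite fold). The adjustment, random lists and trend removal were tested on simulated values for 12418 genes, 200 of them changed by a log2 fold change of 1. With a noise SD of 0.3, 31.0% of the changed genes were recovered, against 36.7% that the normal law gives at that limit, and 3.12% of calls were false. A lower noise SD of 0.2 was added after that first recovery had been seen; it gave 96.5%, against 95.0% by the normal law. These simulations check the code and do not give the power of the authors' test. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.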

Results

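Gene expression was compared between mouse BC CML cells in which Amd1 had been targeted by a short hairpin RNA (shAMD1, 3 libraries) and cells with a control hairpin against lacZ (shlacZ, 3 libraries). Blast crisis is the acute, blast-rich phase of chronic myeloid leukaemia. Amd1 encodes S-adenosylmethionine decarboxylase, which makes the aminopropyl donor for spermidine and spermine synthesis. Each group had a single pooled FPKM value per gene, over libraries numbered 2 to 4 for shAMD1 in the table and 1 to 3 in the labels, so values below are the authors' group values without an SD, and the test is the authors' own. Sequencing depth is unknown.

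The target itself was lower in shAMD1 in value but did not pass the test. Amd1 (chromosome 10, 40287458 to 40302188, GRCm38, protein coding) had an FPKM of 25.9 in shlacZ and 15.7 in shAMD1, with a log2 fold change of -0.72 and an adjusted p of 0.733 in the authors' deposited table. Amd2, a near-identical copy of Amd1, had an FPKM of 42.8 in shlacZ and 16.7 in shAMD1, with a log2 fold change of -1.36 and an adjusted p of 0.357 in the authors' deposited table. Both rows carry the locus of Amd1, whereas RefSeq places Amd2 at 35708691 to 35711891 on the same chromosome, so the split of reads between the copies is uncertain. The sum of both rows was 68.8 in shlacZ and 32.4 in shAMD1, which is 52.9% lower and has no test. Both rows were lower in value in the group that the labels name as the knockdown, and neither passed the authors' test.

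Across the transcriptome, shAMD1 cells had higher levels of many mature granule, ATF4 target, p53 target, NF-kB and immediate early genes, and lower levels of a part of the stem and progenitor regulators. By the authors' deposited table, 1665 of 12425 tested genes were called, 960 of them higher and 705 lower in shAMD1. Rises were larger than falls. Among called genes with at least a 2-fold difference, 497 were higher and 167 lower. The median log2 fold change of tested genes in the authors' deposited table was close to 0 (-0.0018). A filter on mean FPKM of at least 5 left 966 called genes, as 650 of the called genes lay under that level and 49 more were lost when the adjustment was repeated. Y-linked genes, chosen after their values were seen, also differed between the groups. Eif2s3y had an FPKM of 0.0543 in shlacZ and 8.82 in shAMD1, while the X-linked Xist RNA had 62.9 and 52.8.

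**Figure D1:**
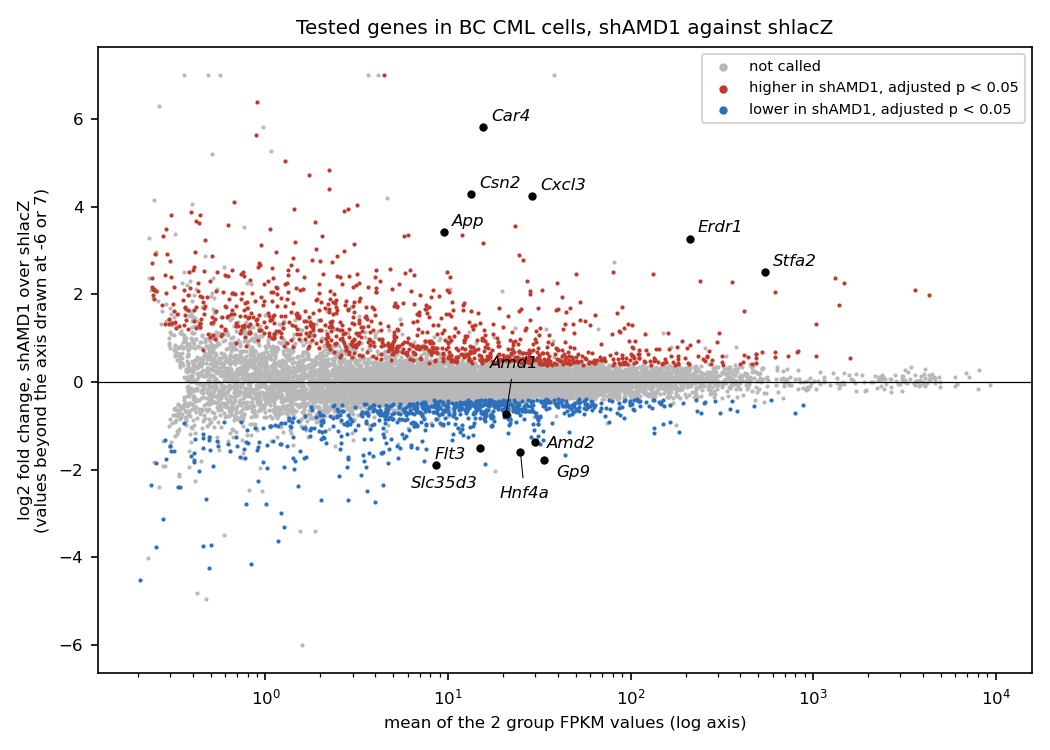
Log2 fold change (shAMD1 over shlacZ) of each tested gene against the mean of its 2 group FPKM values on a log axis. Red points are the genes called higher, blue points those called lower and grey points those not called in the authors' deposited table, with 12 genes named in black. Car4 stands highest of these 12 at 5.83, and neither Amd1 nor Amd2 was called.

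Among called genes with a mean FPKM of at least 5, without placeholder, pseudogene and non-coding RNA symbols, the largest rise was that of Car4, a membrane-bound carbonic anhydrase, from an FPKM of 0.535 to 30.4 (56.8-fold). Next were the milk casein gene Csn2 (1.30 to 25.3, 19.5-fold) and the neutrophil-attracting chemokine gene Cxcl3 (2.90 to 55.1, 19.0-fold). App, the amyloid precursor protein gene, rose 10.8-fold, the chemokine gene Ccl1 10.3-fold, the casein gene Csn1s2b 10.1-fold and Cxcl2 7.46-fold. Erdr1, a gene of the pseudoautosomal region that RefSeq annotates as a transcribed pseudogene, rose from 39.5 to 382. Bcl2a1b, an anti-apoptotic BCL2 family gene, rose 10.2-fold, and the copies Bcl2a1d and Bcl2a1a rose 16.6-fold and 14.9-fold from values under 1. These copies are near-identical, so their reads may have been shared. Rprm, a cell cycle inhibitor gene, rose 5.94-fold. Each of these genes had an adjusted p of 0.000972, the smallest in the authors' deposited table.

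With the same limits, falls were led by Slc35d3, a gene of platelet dense granule formation, from 13.6 to 3.67 (3.71-fold lower). Among transcription factor genes, Hoxd4 fell from 11.4 to 3.27, Zbtb16 from 8.14 to 2.44, Hnf4a from 37.5 to 12.4, Hoxa10 from 8.04 to 2.85 and Foxc1 from 9.22 to 3.32. The receptor gene Flt3 fell from 22.2 to 7.76 and Pdgfrb from 9.11 to 3.38. The remaining members were Gp9, the fatty acid transporter family gene Slc27a3 (2.90-fold lower), the methionine sulfoxide reductase gene Msrb3 (2.82-fold lower) and the tetraspanin gene Tspan8 (2.74-fold lower). All 12 had an adjusted p of 0.000972 in the authors' deposited table.

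Many genes of the integrated stress response, targets of the transcription factor ATF4, were called higher. Of 38 tested members, 25 were called higher and none lower in the authors' deposited table, and 32 were higher and 1 lower when adjusted over the list alone. Random lists matched on expression reached at most 10 members higher. The list's median log2 fold change was 0.58, at the 100th percentile of random lists. Trib3, a pseudokinase gene, rose from 6.52 to 45.2, Atf3 from 0.458 to 3.14 and the mitochondrial folate enzyme gene Aldh1l2 from 0.253 to 1.56. Endoplasmic reticulum chaperone and unfolded protein genes had 3 of 22 members called higher and none lower, which included Xbp1 (106 to 179), with 3 higher when adjusted over the list alone. Of 16 heat shock genes, Hspa1a (1.88 to 8.90) and Hspa1b (2.85 to 11.3), which are near-identical copies, were called higher, and the list's median log2 fold change was 0.02.

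p53 target genes had 19 of 32 tested members called higher and 2 lower in the authors' deposited table, with 22 higher and 2 lower when adjusted over the list alone, against at most 8 higher in random lists. The median log2 fold change was 0.67. Phlda3, an inhibitor of AKT, rose from 11.1 to 45.1, Plk2 from 0.890 to 3.15 and Psrc1 from 22.03 to 66.5. Cdkn2a, which encodes the cell cycle inhibitors p16 and p19Arf, rose from 19.3 to 60.9. It is on the fixed list and was counted, though it is not an established p53 target. Trp53inp1 and Sulf2, chosen after their values were seen, fell from 13.2 to 6.86 and from 15.5 to 10.9. With a 1.5-fold limit and an adjusted p under 0.1, 1 member was lower. Among BCL2 family and caspase genes, 7 of 30 were higher and 1 lower, or 7 and 2 when adjusted over the list alone, and the pro-apoptotic gene Bbc3 rose from 11.9 to 28.3.

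Many inflammatory and early-response genes were called higher as well. The NF-kB list had 17 of 30 members called higher and none lower in the authors' deposited table, with 21 higher when adjusted over the list alone, and a median log2 fold change of 0.86. The receptor gene Tlr4 rose from 0.0933 to 0.725, at a low level in both groups, and Il1rn, which encodes the interleukin-1 receptor antagonist, from 5.46 to 19.0. Of 24 immediate early genes, which respond to stimuli within minutes, 16 were called higher and none lower, and 19 were higher when adjusted over the list alone. Their median log2 fold change was 0.71. Egr1 rose from 18.9 to 58.8, Egr3 from 2.73 to 6.60 and Jun from 18.5 to 41.8. Random lists matched to either list reached at most 8 members higher. Type I interferon genes were mixed, with 4 of 38 higher and 2 lower, the same counts when adjusted over the list alone, and Slfn1 rose from 2.04 to 11.05 while Ifi47 fell from 83.7 to 53.1. Monocyte and macrophage markers, 11 of 24 called higher and 1 lower (19 and 1 when adjusted over the list alone), moved with these lists.

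**Figure D2:**
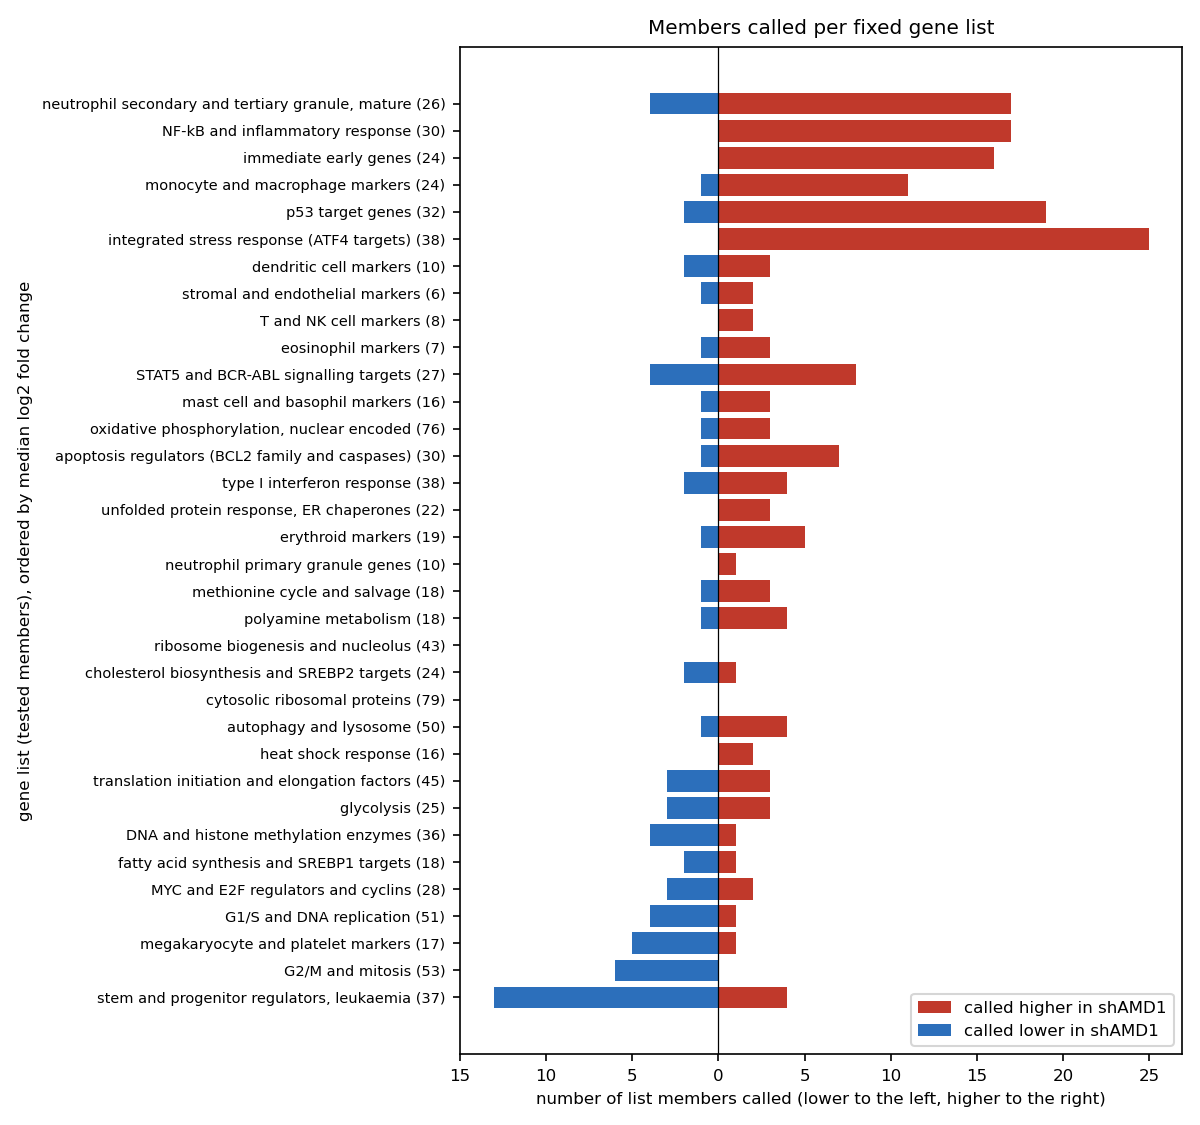
Number of members called higher (red, to the right) or lower (blue, to the left) in shAMD1 for each fixed gene list with at least 5 tested members, by the authors' deposited table. Lists are ordered by median log2 fold change, with the number of tested members in parentheses. The list of ATF4 targets has 25 members higher, and the stem and progenitor list has 13 lower.

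Genes of mature neutrophil granules had the highest median of the 34 fixed lists tested, with a log2 fold change of 1.07. Of 26 members, 17 were called higher and 4 lower in the authors' deposited table, and 18 higher and 4 lower when adjusted over the list alone. The stefin genes Stfa2 and Stfa1, which are similar copies encoding cysteine protease inhibitors, rose from 162 to 925 and from 424 to 2208. Retnlg rose from 24.1 to 137, and Camp, which encodes the antimicrobial peptide cathelicidin, from 123 to 595. The members that fell, chosen after their values were seen, were Hp (300.2 to 184.7), Itgam (34.3 to 21.8), Anxa1 (261 to 196) and Cxcr2 (11.6 to 8.31). With a 1.5-fold limit and an adjusted p under 0.1, 2 members were lower. Primary granule genes, which are made earlier in granulocyte development, had 1 of 10 members called higher, Ctsg (206 to 390), and a median log2 fold change of 0.12, with the same count when adjusted over the list alone. Elane and Prtn3, chosen after their values were seen, share a merged locus of 48 rows in the table and were not called.

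**Figure D3:**
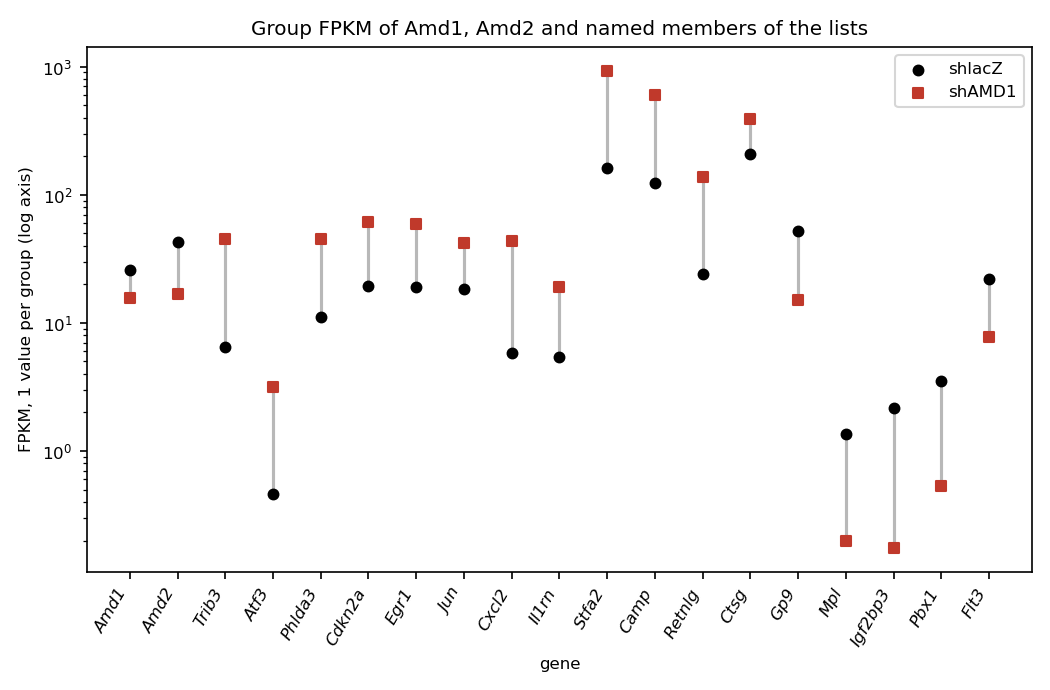
FPKM of chosen genes in shlacZ (black circles) and shAMD1 (red squares), a single pooled value per group on a log axis, so no error bars can be drawn. Stfa2 stands at 162 and 925, and Igf2bp3 at 2.17 and 0.176.

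Stem and progenitor regulators fell for the larger part of the called members. Of 37 tested members in the authors' deposited table, 13 were lower and 4 higher, and when adjusted over the list alone 15 were lower and 5 higher. With a 1.5-fold limit and an adjusted p under 0.1, 8 were lower and 2 higher, and with a mean FPKM of at least 5, 2 were higher. Random lists at the main threshold reached at most 9 lower, and the median log2 fold change was -0.27, below all random lists. Igf2bp3, an RNA-binding protein gene of fetal haematopoiesis, fell from 2.17 to 0.176 (12.3-fold lower), the thrombopoietin receptor gene Mpl from 1.36 to 0.197 and Pbx1 from 3.49 to 0.537. Bcat1, a branched-chain aminotransferase gene, rose from 1.24 to 4.18. Megakaryocyte and platelet markers had 5 of 17 members lower and 1 higher, or 6 and 3 when adjusted over the list alone, and random lists reached up to 6 lower. With a mean FPKM of at least 5, 3 were lower, and with the 1.5-fold limit 2 were higher. The receptor glycoprotein genes Gp9 (52.2 to 15.1), Gp1bb (45.3 to 20.8) and Gp1ba (10.1 to 4.75) were lower.

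Cell cycle lists had low medians and few called members. For G1/S and replication genes, 4 of 51 were lower and 1 higher in the authors' deposited table, the same counts when adjusted over the list alone, and the median log2 fold change was -0.15, at the 0.02th percentile of random lists. E2f8 fell from 68.8 to 45.2 and Mcm6 from 172 to 129.8, while Ccne1 rose from 12.03 to 18.2. Of 53 G2/M genes, 6 were lower and none higher, again equal to the counts when adjusted over the list alone, with a median of -0.20, below all random lists. Hmmr fell from 15.4 to 10.2. In the list of MYC, E2F and cyclin genes 2 of 28 were higher and 3 lower, also when adjusted over the list alone. Cdkn2b, which encodes the inhibitor p15, rose from 3.96 to 16.4, Ccnd1 fell from 4.42 to 1.15 and Ccnd2 rose from 16.0 to 37.5.

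Some polyamine and methionine genes were called, and neither Amd1 nor Amd2 was among them. Of 18 polyamine genes in the authors' deposited table, 4 were higher and 1 lower, with 5 higher and 2 lower when adjusted over the list alone. Random lists matched on expression had a mean of 1.27 higher and 0.925 lower, and at most 7 and 6. Arg1, which makes ornithine, rose from 8.05 to 16.8, Sat1, the acetyltransferase that starts polyamine breakdown, from 56.9 to 80.6, and the polyamine transporter gene Atp13a3 from 20.4 to 28.8. Odc1, which encodes the enzyme that makes putrescine and was chosen after its values were seen, rose from 178 to 238 with an adjusted p of 0.0257 in the authors' deposited table. The oxidase gene Paox fell from 30.99 to 20.2. Spermidine synthase (Srm, 244 and 256) and spermine synthase (Sms, 34.4 and 36.2), also chosen after their values were seen, were not called. In the methionine list 3 of 18 were higher and 1 lower, the same counts when adjusted over the list alone. Its random lists had a mean of 1.48 higher and 0.983 lower, and at most 8 and 6. Cth rose from 1.11 to 5.13 and Slc7a5 from 72.8 to 138.7, both also on the ATF4 list, and Ahcy fell from 157 to 105.

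Translation genes showed little change. None of 79 ribosomal protein genes and none of 43 ribosome biogenesis genes passed the authors' test, over all genes or when adjusted over the list alone, while 1 and 3 members had an unadjusted p under 0.05 in the authors' deposited table. Of 45 initiation and elongation factor genes, 3 were higher and 3 lower, also when adjusted over the list alone. Pabpc1, the poly(A)-binding protein gene, fell from 987 to 606, Eif4ebp1, a translation repressor gene, rose from 82.2 to 125, and Eif4ebp2 fell from 67.8 to 46.9.

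The remaining pathway lists with tested members had called members in both directions, though some had medians above most random lists. Of 27 STAT5 and BCR-ABL target genes in the authors' deposited table, 8 were higher and 4 lower (9 and 4 when adjusted over the list alone), with Id1 going from 83.4 to 138 and Dusp4 from 0.679 to 2.08. The median log2 fold change of that list was 0.23, at the 99.97th percentile of random lists. Nuclear genes of oxidative phosphorylation had 3 of 76 higher and 1 lower, also when adjusted over the list alone, and a median log2 fold change of 0.17, at the 99.99th percentile of random lists. In value, 63 of the 76 members were higher in shAMD1. Uqcrq rose from 381 to 594. Glycolysis genes were 3 of 25 higher and 3 lower, cholesterol genes 1 of 24 higher and 2 lower, and both lists had equal counts when adjusted over the list alone. Fatty acid genes were 1 of 18 higher and 2 lower (2 and 3 when adjusted over the list alone), and lysosome and autophagy genes 4 of 50 higher and 1 lower (3 and 1). DNA and histone methylation enzymes were 1 of 36 higher and 4 lower, the same when adjusted over the list alone, among them Dnmt3a (8.35 to 5.23) and Dnmt3b (13.1 to 9.01). None of the mitochondrially encoded mRNAs was found in the table.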

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

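The tests of a few genes taking most of the counts, of handling, of admixed neutrophils and of the Y-linked genes were chosen after the results were seen. The length and GC test was fixed before its own result but after the fold changes had been seen. Untested genes were looked at separately, since the comparison above leaves them out. Of the genes that the authors' deposited table marks as not tested, 10 had an FPKM of at least 1 in either group, and 4 of these, all small RNA genes, had at least 1 in shAMD1 and a higher value than in shlacZ. Mir6981 was listed at 0 in shlacZ and 43.9 in shAMD1, Snora23 at 0 and 1.66, Mir6340 at 63.1 and 69.1, and Snora28 at 20.7 and 22.4. These differences have no test.

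Of the 120 tested members of the ATF4, p53, NF-kB and immediate early lists, 73 were called higher and 2 lower in the authors' deposited table, with a median log2 fold change of 0.68. Removing the trend on transcript length and GC content left a median of 0.64, against 0.05 at the upper end of the central range of random lists treated alike, which argues against that trend as the whole cause. A few abundant transcripts taking most of the counts would shift all other genes alike, whereas the lists' median lay 0.69 above the median of all tested genes, a distance that no common scaling changes. Handling of the cells before lysis stays open: the 18 immediate early genes on no other list had a median of 0.709, the heat shock list had a median of 0.02, and handling of the groups cannot be told apart from the hairpin. A response to the Amd1 hairpin may underlie the pattern, as a hypothesis, and an effect of the hairpin on another transcript was not tested. Of 24 monocyte and macrophage markers, 11 were called higher and 1 lower, with a median log2 fold change of 0.71. The NF-kB list shares Cd14 with that list. Whether a changed share of myeloid cell types underlies part of the NF-kB rise was not tested either.

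Of 26 mature granule genes, 17 were called higher and 4 lower in the authors' deposited table, and the median log2 fold change was 1.07, which stayed at 1.07 after the length and GC trend was removed. Admixed mature neutrophils alone would lower other genes no further than by dilution. The primary granule genes had a median 0.82 above the log2 fold change of Hp, the list member that fell most. Hp was picked as the lowest of 26 members after its values were seen. Itgam (-0.65), Cxcr2 (-0.48) and Anxa1 (-0.42), the other members called lower, also lay below the lower quartile of the primary granule genes (0.0044). If the primary granule genes gauge dilution, these 4 falls argue against admixture alone for these 4 members, which were picked after their values were seen. The falls do not bear on the members that rose. For the 17 members that rose, admixture cannot be told apart from maturation of the leukaemic cells, since no profile of the admixed cells was at hand. The Y-linked genes described next may come from male cells in part of the shAMD1 material. Whether such cells carry the granule rise cannot be told without values per library. S100a8 (1755 to 6922) and S100a9 (1365 to 5877), chosen after their values were seen, are abundant in neutrophils and were high in both groups. The cells were sorted, by markers that the labels do not name.

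Y-linked genes were near 0 in shlacZ and present in shAMD1. Eif2s3y went from 0.0543 to 8.82 and Ddx3y from 0.0214 to 1.78, with adjusted p of 0.0108 and 0.0121 in the authors' deposited table, while Kdm5d (0.00588 to 0.966) and Uty (0.00245 to 0.712) were not called. The ratio of Y to X copy rose at least 86.7-fold over 4 pairs, which argues against reads of the X-linked copies as the source. It does not exclude them, since the shlacZ ratios rest on Y values near 0. Xist in shAMD1 was 83.9% of its shlacZ value, which argues against all shAMD1 cells being male. Male cells in part of the shAMD1 material may be the source, but this cannot be told from these values, since the Xist difference had a p of 0.1085 in the authors' deposited table and no value per library was analysed here. The groups would then differ in the sex of their cells as well as in the hairpin.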

How the results depend on the processing

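The removal of rows with a shared locus, the sum of the Amd1 and Amd2 rows, and all list alternatives except the filter on mean FPKM were chosen after the data were examined, the length and GC trend before its own result was seen. No large list median changed its sign. A change of sign was not looked for in small list medians or in counts. The count of 1665 called genes lay within 1.5 times under 4 alternatives (1385 to 1593). Centring leaves the authors' p-values as they are and tests nothing for this count. With a mean FPKM of at least 5, 966 were called, 502 higher and 464 lower, and all 966 were among the 1665; fewer genes were tested (8450), 650 called genes lay under the limit and 49 were lost to the repeated adjustment. The sum of the Amd1 and Amd2 rows had a log2 fold change of -1.09, as the Amd2 row had the larger difference. At a mean FPKM of at least 5, list medians moved to 0.45 (ATF4), 0.69 (NF-kB) and 1.19 (mature granule), 2 stem and progenitor genes were higher and 3 platelet markers lower. On the log2(FPKM + 1) scale, the medians were 0.67 (NF-kB) and 0.94 (mature granule), since that scale shrinks the change of low genes. Under a 1.5-fold limit with an adjusted p under 0.1, 1 p53 gene was lower, 2 stem and progenitor genes higher and 8 lower, 2 mature granule genes lower and 2 platelet markers higher. Adjusted over the list alone, 1 ATF4 gene was lower and 3 platelet markers higher. Apart from the construction named, the cause was not tested. The main lists here were the ATF4, p53, NF-kB, immediate early, mature granule, stem and progenitor, and platelet lists. Values of single named genes and of all other lists, the largest among them, moved in 128 of the alternatives and did not in 598. No paired analysis was possible because the authors' tables give a single value per group. For the same reason, TMM, RLE and library-total scaling, limma-voom, list tests with a preset or estimated correlation, rotation tests, the removal of each library in turn and other splits of the 6 libraries were not run, so it is unknown whether a single library carries any result. Depth is unknown and limits low genes to an unknown degree.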

Other observations

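After the data were seen, 9 gene families were read from their symbols, and they overlap the fixed lists in part. MHC class I genes, which present peptides to T cells, had 9 of 15 members called higher and none lower in the authors' deposited table, with a median log2 fold change of 0.66. H2-Q7 rose from 17.3 to 66.7 and H2-K1 from 476 to 763, and the H2-Q genes are similar copies, so the split of reads between them is uncertain. Chemokine ligand genes had 7 of 16 higher and none lower and a median of 1.23, among them Ccl3 (100.5 to 219.6) and Ccl4 (14.0 to 30.8), and 4 of the 7 are also on the NF-kB list. Of 19 cytosolic aminoacyl-tRNA synthetase genes, 7 were higher and none lower, with Aars from 47.6 to 75.8, and 4 of the 7 are also on the ATF4 list. Granzyme, cathepsin and stefin genes had 11 of 29 higher and none lower. Several families went both ways. Interleukin and interferon receptor genes had 9 of 33 higher and 3 lower, guanylate-binding and Slfn genes 3 of 11 higher and 1 lower, and Hox genes 1 of 26 higher and 2 lower. Integrin genes had 2 of 20 higher and 4 lower, with a median of -0.17 at the 1.12th percentile of random lists. Histone genes had a median log2 fold change of 0.21, at the 99.85th percentile of random lists, and 0 of 55 called, with 5 at an unadjusted p under 0.05 in the authors' deposited table.

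Called markers of other blood cells were mixed. The dendritic cell list had a median log2 fold change of 0.56, at the 99.99th percentile of random lists. The mast cell and basophil list had a median of 0.21, at the 97.54th percentile. Medians of the eosinophil, erythroid, T and NK, and stromal lists were positive but within the central range of random lists. By the authors' deposited table, dendritic cell markers had 3 of 10 higher and 2 lower (6 and 2 when adjusted over the list alone), mast cell and basophil markers 3 of 16 higher and 1 lower (4 and 1), and eosinophil markers 3 of 7 higher and 1 lower (3 and 1). Mcpt8, a basophil protease gene, fell from 182 to 88.2, and Prg2, which encodes eosinophil major basic protein, from 182 to 124, while Hdc rose from 132 to 229. Erythroid markers had 5 of 19 higher and 1 lower (5 and 2), with Car2 rising from 160 to 307 and Gata1 falling from 55.1 to 34.8. T and NK markers had 2 of 8 higher and none lower (2 and 0), stromal and endothelial markers 2 of 6 higher and 1 lower (3 and 1), and none of 3 tested B cell markers was called.

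Very large differences were not always called. With at least an 8-fold difference and a finite fold, 38 tested genes were called higher and 9 lower in shAMD1, while 23 were not called in the authors' deposited table, 16 of them higher. Hba-a2, an alpha-globin gene chosen after its values were seen, went from 0.00657 to 75.7 with an adjusted p of 0.502 in the authors' deposited table. Its locus is shared with another row, so reads may have been split between the rows and the size of this difference is uncertain.

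Rmrp and Rpph1, the RNA components of the RNase MRP and RNase P enzymes, left out of the largest rises as non-coding RNAs and chosen after their values were seen, were called higher in the authors' deposited table, from 3.08 to 27.9 and from 3.26 to 17.2.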
